A study of Mus musculus with 7 samples.

How the data were processed

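Expression was measured in the hypothalamus of 3-month-old mice on Affymetrix mouse430_2 arrays, 1 array per sample, with 4 wild-type samples and 3 samples from mice that lack Creb in Pomc-expressing cells. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on miRNeasy columns and labelled with biotin from 100 ng of RNA. The labels number the samples of each genotype as biological replicates, and do not say whether a sample holds RNA of 1 or of several mice.

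The values used are the log2 expression values the authors deposited. R 2.10.0, affy and RMA are named in the submitters' processing notes, without their order or settings. RMA in its usual form corrects the background, makes the intensity distributions of all arrays equal, and summarises the probes of a probe set by median polish. At the level of probes it therefore removes any difference in overall signal between arrays. It gives no detection call, so that a low value cannot be told from background. Array medians lay between 6.19 and 6.24, and the correlation between arrays over probe sets lay between 0.994 and 0.997. Upper quartiles over probe sets were lower in every knockout array (8.32 to 8.33) than in any wild-type array (8.34 to 8.36). Genes were also put in 10 bins by mean level. The median knockout minus wild-type log2 difference ran from 0.036 in the 2nd dimmest bin to -0.016 in the 7th. A small trend with level thus remained between the groups. The number of arrays limits the precision. The median standard error of a gene's log2 difference was 0.073.

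The table held 45101 probe sets. The 64 control probe sets were left out of the tests, which leaves 45037. Of these, 34945 carried 1 gene symbol, 932 carried several and 9160 had none in the platform annotation used here. No gene was named from a probe set with several symbols. Gene identifiers of 34741 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table was used only for names and for the order of genes along chromosomes, since the genome build behind the array annotation is not given in the sources used here. For tests per gene, the probe set with the highest mean over all 7 arrays stood for its gene, which gave 18193 genes.

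Knockout was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. All log2 differences are knockout minus wild type. Standard errors are limma's, and SDs are over arrays. Gene groups were tested with camera at a preset correlation of 0.01 between genes, adjusted over 30 gene lists, and again with a correlation estimated from the arrays. The tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Additions made later are named in the closing section.

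Named genes follow a fixed rule. It takes Creb1 and Pomc with every probe set. It takes up to 12 genes with the largest rise and 12 with the largest fall among genes past the threshold whose knockout and wild-type values do not overlap, filled to 8 in each direction with non-overlapping genes of the smallest unadjusted p. Symbols that name only a clone or a prediction were skipped there. Up to 4 members of each list with the smallest unadjusted p complete the rule, with any member past the threshold within its list. As applied, 4 members were named for 12 lists, those that passed and those closest to the question. For each other list a single member was named, so the number named depended on whether a list passed. A few further genes and probe sets were chosen after their values were seen, and are said to be so.

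Sex was not in the labels and was read from Xist and 3 Y-linked transcripts. The gene-level fit was tested on simulated data with the spread of these arrays over 18193 genes. It recovered 71.9% of changes of 0.5 and 96.2% of changes of 1 on the log2 scale, and called 0.1 genes and 0.1 lists on average where nothing was changed. The simulated genes varied independently of each other, with no structure shared between arrays. These rates therefore do not measure false calls where genes vary together. In the real arrays, 17 of the 35 splits into 4 and 3 called at least 8 lists. Alternatives covered the filter on dim probe sets, the variance model, array weights, normalization, the choice of probe set, sex as a covariate, the replicate number as a block over the arrays numbered 1 to 3, the thresholds, the camera settings and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.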

Results

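The data were 7 expression arrays of mouse hypothalamus at 3 months of age, 4 from wild-type mice and 3 from mice in which Creb was deleted by a Cre recombinase expressed in Pomc cells. Creb1 encodes a transcription factor that acts downstream of cyclic AMP. Pomc encodes the precursor of the appetite-suppressing melanocortin peptides, which is made by a group of neurons in the arcuate nucleus. The comparison asks which hypothalamic genes depend on Creb in those appetite-controlling neurons. Replicates are separate biological samples per the labels.

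Creb1 mRNA in the whole hypothalamus was 9.49 ± 0.083 (SD, n = 4) in wild type and 9.45 ± 0.027 (SD, n = 3) in the knockout on the log2 scale, a difference of -0.04 ± 0.052 (SE), which did not pass (limma, adjusted p = 0.787). Wild-type arrays read 9.44, 9.57, 9.40 and 9.56, and knockout arrays read 9.42, 9.46 and 9.47. The 6 Creb1 probe sets differed by -0.11 to 0.18, and 0 of them passed the threshold. Pomc was 9.67 ± 0.45 (SD, n = 4) in wild type and 9.88 ± 0.36 (SD, n = 3) in the knockout, and the difference of 0.21 ± 0.24 (SE) did not pass (limma, adjusted p = 0.765). The other Pomc probe set differed by 0.22. Leaving out an array moved the Creb1 difference between -0.071 and -0.016, and that of Pomc between -0.0022, without knockout array 1, and 0.41, without wild-type array 1. These values do not check the genotype labels: Pomc cells are a small part of the tissue, and the position of the Creb1 probe sets relative to the deleted part is not given in the sources used here.

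Efr3b and Snhg14 were the 2 genes of 18193 that passed the threshold. Efr3b was higher in the knockout, and Snhg14 was lower, with 1 of its 3 probe sets past the threshold. Efr3b encodes a plasma membrane protein that anchors a phosphatidylinositol kinase. Its level rose from 10.96 ± 0.084 (SD, n = 4) to 11.83 ± 0.014 (SD, n = 3), a log2 difference of 0.88 ± 0.046 (SE) or 1.84-fold, and all 3 knockout arrays lay above all 4 wild-type arrays (limma, adjusted p = 0.000365). A dimmer Efr3b probe set was also higher, by 0.66 ± 0.088 (SE), and did not pass over all probe sets (limma, adjusted p = 0.0944). Snhg14, a long noncoding RNA of an imprinted region, had a probe set that fell from 11.05 ± 0.080 (SD, n = 4) to 9.76 ± 0.21 (SD, n = 3), a log2 difference of -1.29 ± 0.089 (SE), again with no overlap (limma, adjusted p = 0.0018). The other Snhg14 probe sets differed by 0.10 and -0.21, and with the mean of its probe sets the Snhg14 call was lost (adjusted p = 0.149).

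At the level of probe sets, 3 of 45037 passed, 2 up and 1 down. Beside Efr3b and Snhg14 this was probe set 1441460_at, unnamed here, which rose from 3.69 ± 0.19 (SD, n = 4) to 5.25 ± 0.15 (SD, n = 3), by 1.56 ± 0.12 (SE) on the log2 scale (limma, adjusted p = 0.00382). Its wild-type level was dim and cannot be told from background, which limits what the size of the rise shows. With the dimmer probe sets dropped, 2 probe sets passed. An unadjusted p under 0.05 was reached by 2131 genes (11.7%), 1018 higher and 1113 lower. Genes with a difference of at least 1.5-fold and an unadjusted p under 0.05 numbered 44, of which 16 were higher and 28 lower. Knockout and wild-type values did not overlap for 2208 genes (12.1%), where independent arrays give 5.71% by chance. Another grouping of the same arrays gave 2431 such genes. The gene count depended on single arrays: 21 genes passed without wild-type array 1, 6 without wild-type array 2 and 8 without knockout array 1. The corresponding probe set counts were 46, 12 and 16, with 9 without knockout array 2 and 5 without knockout array 3, and the count of 44 became 120 without wild-type array 1 and 73 without knockout array 1. Without wild-type array 4 it was 63, and 74 with the replicate number also as a block, a fit that holds only the arrays numbered 1 to 3.

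**Figure D1:**
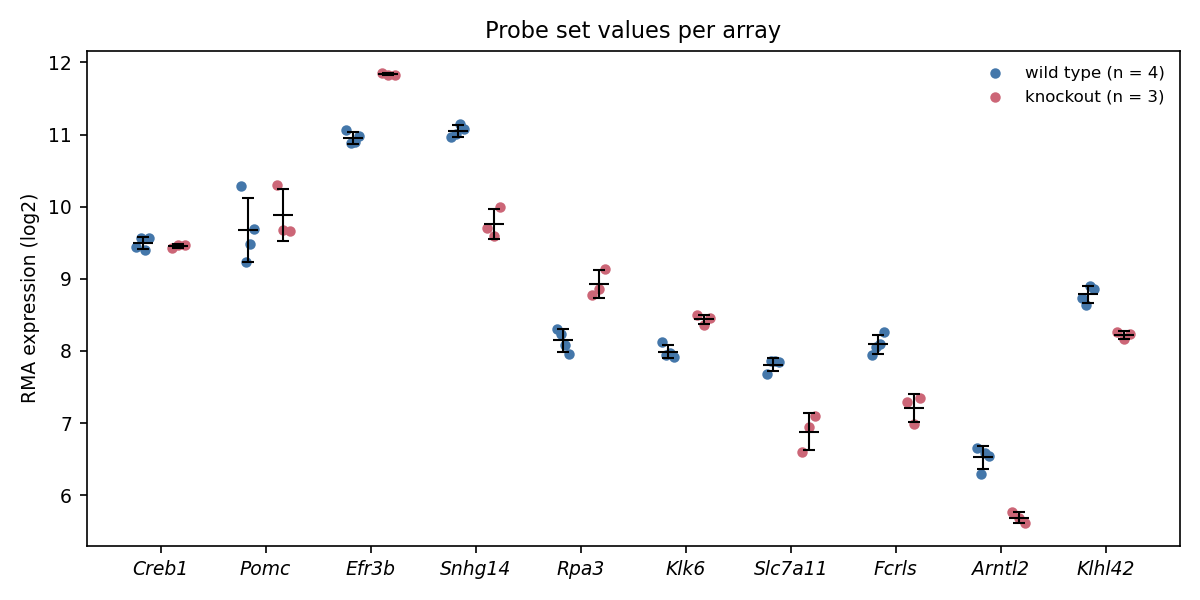
Values per array of the probe sets standing for 10 genes, in log2 units from RMA on the vertical axis, with wild-type arrays in blue and knockout arrays in red; black bars give the mean and SD. Efr3b and Snhg14 separate the groups and passed the threshold, the Creb1 and Pomc values overlap between the groups, and the other 6 genes did not pass.

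None of the other named genes passed over all genes tested. On the higher side, Rpa3, a subunit of the single-strand DNA-binding replication protein A, differed by 0.78 ± 0.11 (SE), and Klk6, a kallikrein serine protease of oligodendrocytes, by 0.45 ± 0.066 (SE). Insrr, a receptor tyrosine kinase related to the insulin receptor, differed by 0.36. The dim transcripts Gzmn, Klra7, Taf7l and Aldoart2, known from lymphocytes or testis, differed by 0.35, 0.38, 0.33 and 0.44, and adjusted p-values of these 7 genes ran from 0.105 to 0.185 (limma). On the lower side, Slc7a11, the cystine and glutamate exchanger, differed by -0.93 ± 0.11 (SE), the microglial receptor gene Fcrls by -0.88 ± 0.11 (SE) and Arntl2, a paralog of the clock factor Bmal1, by -0.84 ± 0.096 (SE). Klhl42 differed by -0.56, the histone methyltransferase gene Kmt2d by -0.34, the chromatin remodeller gene Arid1a by -0.29, and Sik3, a kinase of CREB coactivators, by -0.28. Adjusted p-values of these 7 ran from 0.0616 to 0.105 (limma). The other probe set of Slc7a11 differed by -0.032, that of Arntl2 by -0.073 and that of Kmt2d by -0.0058, and the 3 other Sik3 probe sets differed by -0.00068, -0.0082 and 0.066. The values of Rpa3, Klk6, Kmt2d, Fcrls, Slc7a11 and Sik3 passed without wild-type array 1, Arntl2 without wild-type array 1 or 2, Klhl42 without wild-type array 2, and Slc7a11 also without knockout array 1.

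Of the lists closest to the question, none passed. Among 16 CREB family and coactivator genes, 8 were higher and 8 lower, with a median of -0.0088 (camera, adjusted p = 0.618). The histone acetyltransferase coactivators Ep300 and Crebbp differed by -0.19 ± 0.053 (SE) and -0.15 ± 0.045 (SE), and all 4 Crebbp probe sets were lower. Creb3 differed by 0.14 and Atf7 by 0.20. Among 46 known CREB target genes, 30 were higher, with a median of 0.055 (camera, adjusted p = 0.376). The largest evidence there was for Syn1, a synaptic vesicle protein gene, at -0.12, the peptide gene Ucn at 0.23, the opioid precursor gene Pdyn at 0.31 and the nitric oxide synthase gene Nos1 at -0.15. Among 52 genes of the appetite and melanocortin circuit, 31 were higher, with a median of 0.032 (camera, adjusted p = 0.376). Socs3, an inhibitor of leptin signalling, differed by 0.28 ± 0.10 (SE), and Stat3, its transcription factor, by 0.11, the cholecystokinin receptor gene Cckbr by -0.16 and the orexin gene Hcrt by 0.33. The 21 arcuate nucleus markers had a median of 0.15, with 16 higher (camera, adjusted p = 0.11), and Nkx2-1, Tbx3 and Nhlh2 differed by 0.18, 0.24 and 0.17. The arcuate list passed without wild-type array 1 (0.12), wild-type array 3 (0.14) or knockout array 3 (0.13), and its median was 0.061 without wild-type array 2 and 0.062 without knockout array 1, where it did not pass. The median of the CREB targets was -0.032 without wild-type array 2, 0.10 without wild-type array 3 and 0.0015 without knockout array 1, and that of the appetite circuit 0.019 without wild-type array 3. The CREB family median ran from -0.038 to 0.029 with an array left out. Atf7 and Tbx3 were at 0.14 and 0.15 without knockout array 2, and Nhlh2 at 0.11 without knockout array 1. Adjusted over the list alone, 0 members of these 4 lists passed, as over all genes. Single probe sets of Stat3 and Cckbr went the other way, at -0.16 and 0.21, and the probe sets of Creb3, Atf7, Nos1 and Tbx3 also differed in sign.

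Of the 30 lists, 8 passed with the preset correlation, 3 up and 5 down, and 0 passed with an estimated correlation (lowest adjusted p = 0.578). The adjustment gave all 8 lists that same value. Their unadjusted p with an estimated correlation ran from 0.0435 for ribosomal protein genes to 0.366 for thalamus and habenula markers (camera). The 30 measured cytosolic ribosomal protein genes shifted up as a group, with 29 higher and a median of 0.070 (camera, adjusted p = 5.42e-10; adjusted p = 0.578 with an estimated correlation). Adjusted over the list alone, Rps9, Rps19, Rpl35 and Rpl22 passed, at 0.14, 0.16, 0.11 and 0.098, and 0 passed over all genes tested. One Rps9 probe set went the other way, at -0.48, and one of Rpl22, at -0.055. Of 27 heat shock and unfolded protein genes 22 were higher, with a median of 0.064 (camera, adjusted p = 0.0348; adjusted p = 0.578 with an estimated correlation), with the endoplasmic reticulum proteins Dnajb9 and Pdia4 at 0.13 and 0.20 and the chaperones Hspa8 and Hsp90b1 at -0.056 and -0.085. The other Hsp90b1 probe set was at 0.17. Of 20 lateral hypothalamus and mammillary markers 15 were higher, with a median of 0.10 (camera, adjusted p = 0.0348; adjusted p = 0.578 with an estimated correlation), among them Foxb1 at 0.25, the peptide gene Npvf at 0.78, Foxa1 at 0.31 and Hcrt at 0.33. Npvf was at 0.48 without wild-type array 2, which read 6.30 against 7.25 to 7.73 in the other wild-type arrays. The lateral hypothalamus call was lost without wild-type array 2 (0.064), knockout array 1 (0.051) or knockout array 2 (0.11), and the heat shock call without wild-type array 1 (0.040), 2 (0.048) or 3 (0.067) or knockout array 2 (0.00055). Both calls were also lost with eBayes without a trend, at unchanged medians (0.10 and 0.064), and without wild-type arrays 2 and 3 (0.057 and 0.046). The heat shock call was lost with array weights (0.055) or sex as a covariate (0.062). Within females, with a single knockout array, the heat shock median was -0.029. Calls were kept with larger medians without wild-type array 1 for the lateral hypothalamus (0.16) and without knockout array 1 for heat shock (0.11). The 19 external control probe sets read here, which hold no mouse sequence, were also higher in the knockout arrays, by 0.12.

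Neuron markers shifted down as a group, with 18 of 21 lower and a median of -0.064 (camera, adjusted p = 0.000133; adjusted p = 0.578 with an estimated correlation). Adjusted over the list alone, 4 passed: the neuronal splicing factor gene Rbfox3 at -0.18, the imprinted noncoding RNA Meg3 at -0.14, the neurofilament gene Nefm at -0.18 and Syn1 at -0.12. All 11 Meg3 probe sets were lower. Without wild-type array 2, which had the highest neuron score (0.088), the list passed with a median of -0.040. Of 22 microglia and macrophage markers 18 were lower, with a median of -0.099 (camera, adjusted p = 0.00468; adjusted p = 0.578 with an estimated correlation). Fcrls passed over the list alone. Csf1r, the receptor for a microglial growth factor, differed by -0.16, Fcer1g by -0.16 and Tmem119 by 0.10, or 0.059 without knockout array 2. The microglia median was -0.16 without wild-type array 1, and the call was lost without wild-type arrays 2 and 3 (-0.056), which had the highest microglia scores, 0.12 and 0.054. With a single knockout array within females, the neuron and endothelial calls were lost (-0.024 and -0.0062), and the microglia median was 0.036. Of 21 endothelial and mural cell markers 14 were lower, with a median of -0.069 (camera, adjusted p = 0.0324; adjusted p = 0.578 with an estimated correlation), among them the pericyte receptor gene Pdgfrb at -0.40, Acta2 at -0.34, Slco1a4 at -0.24 and Myh11 at -0.33. Other probe sets were at -0.089 for Pdgfrb, at -0.081 and 0.021 for Acta2 and at 0.24 for Myh11. Slco1a4 was at -0.15 without knockout array 1 and -0.37 without knockout array 2. The endothelial call was lost without wild-type array 4 (-0.078), though not with the replicate number also as a block, without knockout array 3 (-0.015) and with dimmer probe sets dropped (-0.081), and its median was -0.12 without knockout array 1.

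Markers of tissue around the hypothalamus differed most in size. Of 21 meninges and fibroblast markers 19 were lower, with a median of -0.65 (camera, adjusted p = 0.000133; adjusted p = 0.578 with an estimated correlation). Examples were Igfbp2 at -1.17 ± 0.48 (SE), the retinoic acid enzyme gene Aldh1a2 at -1.19 ± 0.56 (SE), Bmp6 at -0.73 and Crabp2 at -0.96. Without wild-type array 3 the list passed with a median of -0.24, and Igfbp2, Aldh1a2 and Crabp2 were at -0.73, -0.71 and -0.54. Of 19 thalamus and habenula markers 17 were lower, with a median of -0.33 (camera, adjusted p = 0.0324; adjusted p = 0.578 with an estimated correlation), among them Amotl1 at -0.17, Adarb1 at -0.33 and Cplx1 at -0.14, with Pou4f1 at 0.27. Probe sets of Adarb1 and of Pou4f1 differed in sign. Amotl1 and Adarb1 were at -0.12 and -0.21 without wild-type array 2, Cplx1 at -0.066 without knockout array 2 and Pou4f1 at 0.055 without knockout array 3. The wild-type arrays differed widely among themselves: meningeal scores, the median of the members' deviations from their means over all arrays, were -0.41, 0.56, 1.23 and -0.29, against -0.42, -0.22 and -0.37 in the knockout arrays. Thalamic scores were -0.23, 0.74, -0.14 and 0.23, against -0.24, -0.33 and 0.045. The thalamic call was lost without wild-type array 2 (-0.11) or 4 (-0.28, with or without the replicate number as a block), and without knockout array 1 (-0.25) or 2 (-0.25). It was also lost with dimmer probe sets dropped, at an unchanged median (-0.33). The thalamic median was -0.16 with the mean of all probe sets. Without wild-type arrays 2 and 3, which had the highest thalamic and the highest meningeal score, 2 of the 30 lists passed, ribosomal protein genes and neuron markers. The meningeal (-0.0085) and thalamic (-0.14) calls were lost, although that choice of arrays lowers both shifts by itself. Both were also lost within females (-0.076 and -0.25), with a single knockout array.

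**Figure D2:**
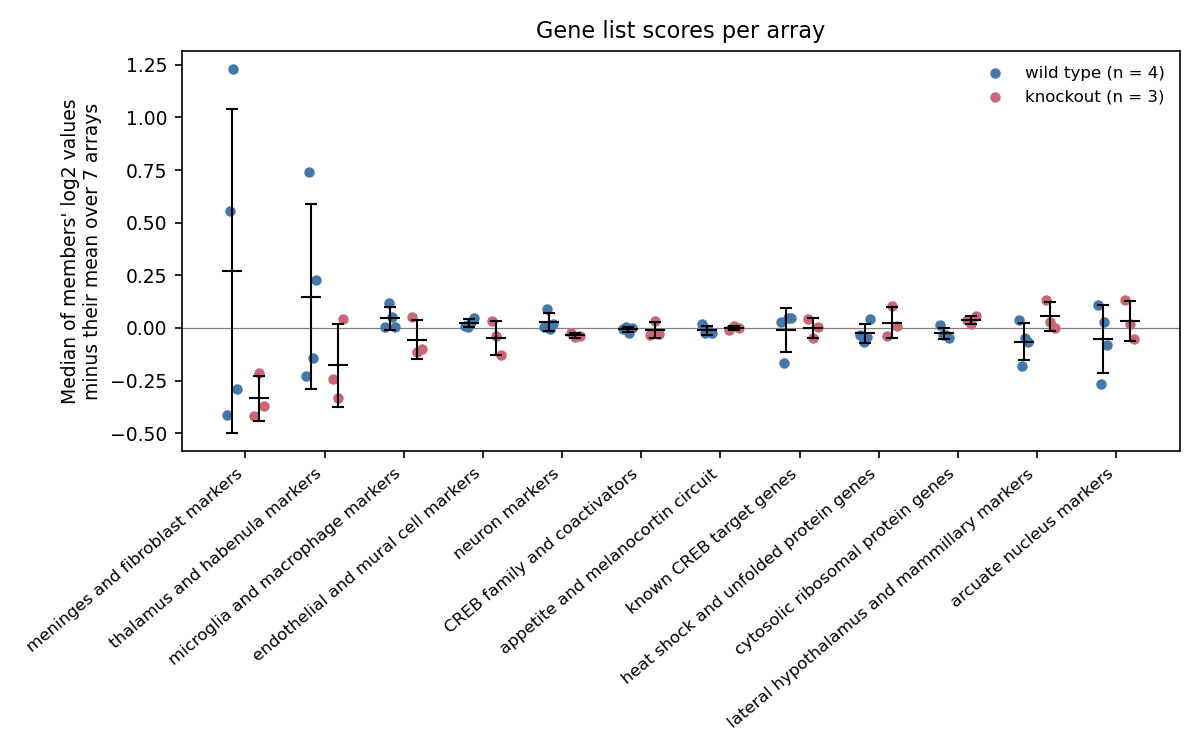
Scores per array of the 8 gene lists that passed and of 4 lists close to the question, as the median over members of the log2 value minus its mean over the 7 arrays; wild-type arrays are blue, knockout arrays red, and black bars give the mean and SD. The meningeal scores of wild-type arrays run from -0.41 to 1.23, and the ribosomal protein scores differ by far less between arrays.

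The remaining 18 lists did not pass. Zfhx3, a transcription factor of the suprachiasmatic nucleus, passed adjusted over its list alone at -0.37 ± 0.072 (SE), not over all genes (limma, adjusted p = 0.203), and all 6 of its probe sets were lower. The suprachiasmatic list had a median of -0.078 (camera, adjusted p = 0.11). Blood cell markers had a median of 0.17 (camera, adjusted p = 0.0695), with Camp at 0.58, and knockout array 2 had the highest score, 0.42. Without that array the blood cell median was 0.080 and Camp was at 0.27. Medians of the other lists with adjusted p-values (camera) were -0.10 and 0.124 for choroid plexus, where Sostdc1 was at -0.23, -0.082 and 0.114 for clock genes, where Clock was at 0.12, and -0.099 and 0.15 for interferon response genes, where Gbp3 was at -0.22. Pituitary markers had 0.061 and 0.15, with Pax7 at 0.30, neuropeptide genes 0.042 and 0.15, with Nmb at 0.34, and oxidative phosphorylation genes 0.020 and 0.105, with Ndufa5 at 0.12. Astrocyte markers had 0.011 and 0.136, with Ppp1r3c at 0.17, oligodendrocyte and myelin markers -0.063 and 0.398, with Hapln2 at 0.38, and ependymal and tanycyte markers -0.00085 and 0.522, with Mia at 0.25. Serotonin and monoamine genes had 0.043 and 0.376, with Dbh at 0.20, ventromedial nucleus markers 0.044 and 0.522, with Rreb1 at -0.45, and paraventricular and magnocellular markers 0.030 and 0.618, with Ebf3 at 0.30. Glucocorticoid response genes had 0.073 and 0.618, with Galnt9 at -0.19, striatum, cortex and amygdala markers -0.023 and 0.522, with Cux2 at -0.26, sex-linked transcripts -0.095 and 0.376, with Kdm5c at -0.17, and immediate early genes 0.019 and 0.943, with Zfp36 at -0.24. The camera direction of the immediate early genes was down, against a median above 0, and that of the ependymal list was up, against a median below 0. Leaving out a single array brought some of these lists past the threshold: neuropeptide (0.074), pituitary (0.099) and oligodendrocyte (-0.10) without wild-type array 1, oxidative phosphorylation (0.024) without wild-type array 3, and glucocorticoid (0.16) and astrocyte (0.038) without wild-type array 4. The same held for blood cell markers without wild-type array 2 (0.16), knockout array 1 (0.30) or knockout array 3 (0.25), for the glucocorticoid list without knockout array 1 (0.18), and for the clock (-0.12) and suprachiasmatic (-0.096) lists without knockout array 3. With the replicate number as a block, besides wild-type array 4 left out, the choroid plexus (-0.15), blood cell (0.17) and sex-linked (-0.091) lists passed, and without the block they did not. Leaving out a single array moved the medians of all 18 lists but the suprachiasmatic and oxidative phosphorylation ones by more than 1.5 times. Ebf3 and Galnt9 were at 0.19 and -0.075 without wild-type array 2, Hapln2 at 0.25 without knockout array 2, Dbh at 0.13 without knockout array 3 and Kdm5c at -0.091 without wild-type array 4, and Zfp36 ran from -0.40 to -0.11. Probe sets of Clock, Pax7, Rreb1, Cux2 and Kdm5c differed in sign.

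Efr3b lies next to Pomc in the order of genes along the chromosome. Other genes within 3 tested genes of Pomc differed less: Dnmt3a by -0.20, Adcy3 by -0.20, Dnajc27 by -0.049, Dtnb by 0.067 and Asxl2 by -0.029, and none of these passed. The neighbours were chosen after the Efr3b value was seen. Efr3b left out, 6 of the 26 other genes within 20 tested genes of Pomc had an unadjusted p under 0.05 (23.1%, against 11.7% of other placed genes), a difference that did not pass (Fisher's exact test, two-sided, p = 0.115). Around Creb1 it was 4 of 40 (10%).

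**Figure D3:**
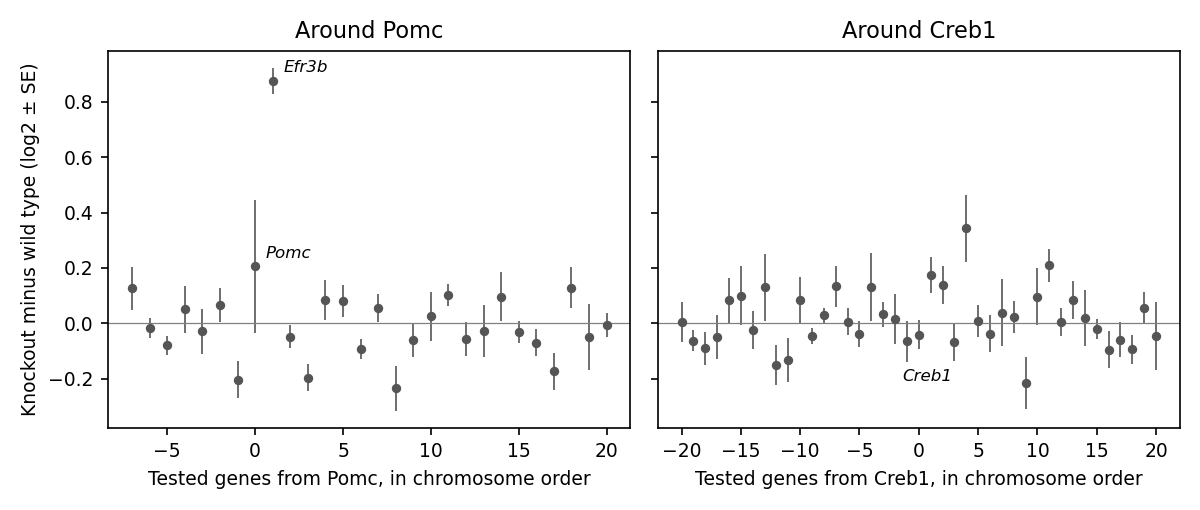
Log2 difference between knockout and wild type, with its standard error, of tested genes in chromosome order around Pomc (left) and Creb1 (right); the horizontal axis counts tested genes from the locus, not bases. Efr3b, at 0.88, stands beside Pomc, and the genes around it differ by far less.

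Both sexes were present in both groups. Wild-type arrays 1 and 4 and knockout array 1 had high Xist, the RNA that silences an X chromosome, and low Y-linked transcripts, and the other 4 arrays the opposite. With genotype held in the model, 5 genes differed between the sexes: Xist, Ddx3x, Kdm5d, Uty and Eif2s3y, listed after their values were seen. Of these, Xist and the Y-linked Kdm5d, Uty and Eif2s3y had served to read the sex. Their difference was fixed by that choice, and only Ddx3x had no part in it. With sex as a covariate 3 genes differed between genotypes, Efr3b, Snhg14 and Slc7a11. A genotype effect that differs between the sexes was found for 0 genes (limma), with 668 at an unadjusted p under 0.05. Within males, 2 arrays against 2, Efr3b alone passed, and Snhg14 was at -1.29, as large as with all arrays. Within females, 2 arrays against 1, 0 genes passed, with Efr3b at 0.83, and the spread of the lone knockout array was taken to be that of the wild-type arrays.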

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

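The regrouping of the arrays was planned, although its criterion was set down after its result was seen, and the other tests of explanations in this part were chosen after the results they bear on were seen. In wild-type array 2, Insrr was lowest in its group at 4.9465, in wild-type array 1 Slc7a11 was lowest at 7.6815, and in wild-type array 4 Pax7 was highest at 4.6451. The score of the known CREB target genes was lowest in wild-type array 2, at -0.163905, and that of the clock genes highest in wild-type array 4, at 0.0470071. Each of these 5 values stood apart from the other 3 wild-type arrays by Dixon's criterion, out of 110 checks, and chance gives 5.5. The 19 external control probe sets read here, which the genotype comparison left out, were higher in the knockout arrays by 0.121667.

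Free regrouping of the arrays, whatever their numbers, does not exclude chance for any of the counts. Of the 35 splits into 4 and 3 arrays, the real one included, 4 called at least 2 genes, and the highest other count was 7. For probe sets 7 of 35 splits called at least 3 (highest other 25), and for genes past 1.5-fold and the unadjusted p, 13 of 35 reached 44 (highest other 144). At an unadjusted p under 0.05, 3 of 35 splits reached the real 2131 genes (highest other 2565), and 2 of 35 reached the real 2208 genes without overlap (highest other 2431). For lists, 17 of 35 splits called at least 8 (highest other 15). The split of wild-type arrays 2, 3 and 4 from the rest gave 7 genes and 144 at 1.5-fold, several times the real count. That split moves only wild-type array 1 across, so it may also carry the genotype contrast and is no grouping free of it. Wild-type array 1 correlated best with knockout array 1 (r = 0.997 across probe sets, which are not independent replicates), a likeness that crosses genotype. The split that follows sex gave 5 genes and holds the differences between the sexes. Such splits raise the counts set against the real one, so these shares do not show that chance gave it. If the replicate numbers pair the samples, which is unsettled, only the 8 splits that part all 3 same-numbered pairs compare with the real one, too few for a share under 5%. The highest of the other 7 was 0 genes against 2, 1007 against 2131 at the unadjusted p and 1095 against 2208 without overlap, but 25 probe sets against 3, 53 against 44 at 1.5-fold and 10 lists against 8.

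Efr3b was higher in every knockout array, and it neighbours the gene whose promoter gave the Cre driver its name. A sequence variant under a single probe set is argued against by the other probe set, higher by 0.66 ± 0.088 (SE). For Snhg14, whose other probe sets differed by 0.10 and -0.21, such a variant was not tested and stays open. Extra copies of several genes around Pomc, raising each, are argued against by the highest value among the other 5 genes within 3 of Pomc, 0.067. Sequence around Pomc carried by the Cre driver, either as part of a transgene or as an inherited flank, stays open. It was raised by the position of Efr3b, so that position is not an independent test of it. An inherited flank could alter further neighbours. Among the other 26 genes within 20 of Pomc the excess at an unadjusted p under 0.05 did not pass (Fisher's exact p = 0.115). A driver that alters Efr3b alone predicts no such excess, so these genes cannot decide on it. A response to the loss of Creb allows the rise of 0.88 too, but sets no size for it. It cannot be told apart from sequence carried by the driver, because every array without Creb also carries the driver per its genotype name. Pomc cells are a small part of the tissue, and Efr3b already read 10.96 in wild type. A rise in those cells alone would have to be far above 1.84-fold there, unless they hold most of the Efr3b mRNA. That share was not measured, and a response in other cells was not tested.

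Most gene lists that passed shifted by small amounts. Of the 64 control probe sets, only 19 external ones, chosen by name, were read here. All 19 were higher in the knockout arrays, by 0.12 on average (8.96 ± 0.036 in wild type against 9.08 ± 0.048 in the knockout, SD, n = 4 and n = 3, exact permutation p = 0.0286, two-sided, the smallest that 35 arrangements give). This is a difference between the groups in signal that is not mouse RNA. It does not point to an overall difference in signal behind the list shifts. RMA in its usual form removes such a difference, and 3 lists passed up and 5 down. Whether the source of the control shift also moved lists was not tested. The 7 hybridization controls, added after labelling, were higher by 0.121 on average, and the 12 poly-A controls, which pass through labelling, by 0.122. A difference in labelling would act on these kinds differently, so it is argued against as the whole source of the control shift. An intensity-dependent trend as the whole cause of the ribosomal protein shift is argued against, since that median was 0.067 after cyclic loess normalization and the list kept its call. Wild-type scores spanned 1.64 for meninges and 0.97 for thalamus, more than the shifts between groups, so that different amounts of adjoining tissue in single dissections may account for both. A change in these tissues with genotype stays open, as do the other lists, none of which passed with an estimated correlation.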

How the results depend on the processing

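The settings within males, within females, without wild-type arrays 2 and 3 and after cyclic loess were added after the data were seen. Efr3b passed in 19 of 20 settings that refit the genes, at log2 differences of 0.77 to 0.94, and missed the threshold within females (0.83, adjusted p = 0.957), where fewer arrays were used and the difference was about as large. Its lowest adjusted p was 9.91e-05. Snhg14 passed in 16 of 20, with adjusted p from 0.000461 to 0.704. With the mean of all probe sets its difference shrank to -0.47 (adjusted p = 0.149). It also missed the threshold within males (-1.29, adjusted p = 0.0869), within females (-1.32, adjusted p = 0.704) and without wild-type arrays 2 and 3 (-1.26, adjusted p = 0.0773), where fewer arrays were used and the difference was as large as with all arrays. Both were called with each array left out in turn. Named genes other than Creb1 and Pomc kept their direction and side of the threshold in 1439 of 1465 combinations with a setting, and lists in 509 of 628. These genes were picked from the same arrays by their p or lack of overlap, and most did not pass with all arrays. Their share was therefore favoured by the choice and does not measure robustness. The ribosomal protein list lost its call only with an estimated correlation, with medians of 0.061 to 0.084 over the settings. Without a detection call, values of dim genes cannot be told from background, which limits what their differences show.

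Values in brackets are log2 differences, medians for lists, and the cause of these changes was not tested. With sex as a covariate, 5 probe sets and 80 genes past fold and unadjusted p passed, with a changed sign for ependymal (0.0080), a lost call for heat shock (0.062) and a gained call for arcuate (0.12) and sex-linked (-0.085). With robust eBayes, 11 probe sets and 7 genes passed. At an adjusted p of 0.1, 17 probe sets and 8 genes passed. Within males, 9 probe sets, 1 gene, 185 genes past fold and unadjusted p and 15 lists passed, with a changed sign for immediate early (-0.099) and ependymal (0.030) and a gained call for arcuate (0.17), glucocorticoid (0.19), neuropeptide (0.10), pituitary (0.10), choroid plexus (-0.095), astrocyte (0.064) and sex-linked (-0.11). Within females, 1 probe set, 0 genes and 5 lists passed, with a changed sign for Fcer1g (0.0081), Aldh1a2 (0.094), appetite (-0.0096), paraventricular (-0.024), glucocorticoid (-0.23), heat shock (-0.029), monoamine (-0.00062), pituitary (-0.0040), striatum and cortex (0.038), astrocyte (-0.0025) and microglia (0.036), a lost call for thalamus (-0.25), neuron (-0.024), endothelial (-0.0062) and meninges (-0.076) and a gained call for suprachiasmatic (-0.15) and immediate early (0.24). The calls for heat shock and microglia were lost there too, and one for glucocorticoid was gained. With a single knockout array these list values have no spread within the knockout and support no call. With array quality weights, 6 genes passed, with a changed sign for CREB family (0.0046), immediate early (-0.0054) and ependymal (0.0054) and a lost call for heat shock (0.055). With the mean of all probe sets of a gene, 1 gene passed, with a changed sign for Creb1 (0.047), Cckbr (0.026), Hsp90b1 (0.041), Rps9 (-0.079), CREB family (0.038) and striatum and cortex (0.0061) and a gained call for clock (-0.070) and interferon (-0.099). With the dimmer probe sets dropped, 26 genes past fold and unadjusted p passed, with a changed sign for ependymal (0.010) and striatum and cortex (0.0066), a lost call for thalamus (-0.33) and endothelial (-0.081) and a gained call for oxidative phosphorylation (0.020) and monoamine (0.066). At 1.2-fold, 465 genes passed. At 2-fold, 14 genes passed. With an estimated correlation, 0 lists passed, with a lost call for lateral hypothalamus (0.10), heat shock (0.064), ribosomal protein (0.070), thalamus (-0.33), neuron (-0.064), microglia (-0.099), endothelial (-0.069) and meninges (-0.65). Without wild-type arrays 2 and 3, 2 lists passed, with a changed sign for Pomc (-0.11), CREB family (0.0055), paraventricular (-0.052), neuropeptide (-0.037), pituitary (-0.021) and oligodendrocyte (0.010) and a lost call for lateral hypothalamus (0.057), heat shock (0.046), thalamus (-0.14), microglia (-0.056), endothelial (-0.077) and meninges (-0.0085). These arrays were picked for their high thalamic and meningeal scores, which lowers both medians by itself. With eBayes without a trend, there was a lost call for lateral hypothalamus (0.10) and heat shock (0.064). After cyclic loess, there was a gained call for oxidative phosphorylation (0.024). After a further quantile normalization, there was a changed sign for ependymal (0.0084).

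With the replicate number as a block over the arrays numbered 1 to 3, and so without wild-type array 4, 74 genes past fold and unadjusted p passed, with a changed sign for ependymal (0.0075), a lost call for thalamus (-0.28) and a gained call for glucocorticoid (0.16), choroid plexus (-0.15), astrocyte (0.038), blood cell (0.17) and sex-linked (-0.091). Leaving out wild-type array 4 without a block gave 63 such genes and the same log2 differences and medians, with the same lost call for thalamus and the same gained calls for glucocorticoid and astrocyte. Among lists, the block itself added the calls for choroid plexus, blood cell and sex-linked and kept that for endothelial, and it changed no call of a named gene. Whether the replicate numbers pair the samples stayed unsettled. Deviations of same-numbered arrays from their group means correlated at 0.323, 0.0767 and 0.179 across genes over the arrays numbered 1 to 3, where the lowest across probe sets was 0.0927. Over all 7 arrays these were 0.318, 0.101 and 0.143 across genes and 0.258, 0.114 and 0.156 across probe sets. Among wild-type arrays 1 to 3, each knockout array's deviations correlated best with those of its own number across genes, but those of wild-type array 2 did so with knockout array 3. Across probe sets over all 7 arrays, wild-type arrays 1 to 3 each correlated best with the knockout array of their own number. This is a hint from the data, and such pairs also share their sex. The block called 2 genes, Efr3b and Snhg14.

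Leaving out each array in turn gave 3 to 46 probe sets, 2 to 21 genes, 36 to 120 genes past fold and unadjusted p and 5 to 11 lists. Log2 differences ran over -0.071 to -0.016 (Creb1), -0.0022 to 0.41 (Pomc), -0.038 to 0.029 (CREB family), -0.032 to 0.10 (CREB target), 0.019 to 0.041 (appetite), 0.061 to 0.14 (arcuate), 0.0030 to 0.067 (ventromedial), -0.043 to 0.072 (paraventricular), -0.11 to -0.054 (suprachiasmatic), 0.051 to 0.16 (lateral hypothalamus), -0.12 to -0.039 (clock), -0.11 to 0.14 (immediate early), -0.080 to 0.18 (glucocorticoid), -0.16 to -0.041 (interferon), 0.00055 to 0.11 (heat shock) and 0.015 to 0.026 (oxidative phosphorylation), and over 0.061 to 0.081 (ribosomal protein), 0.0079 to 0.064 (monoamine), -0.030 to 0.074 (neuropeptide), 0.024 to 0.099 (pituitary), -0.15 to -0.011 (choroid plexus), -0.0026 to 0.040 (ependymal), -0.43 to -0.11 (thalamus), -0.028 to 0.0050 (striatum and cortex), -0.083 to -0.040 (neuron), -0.10 to 0.031 (oligodendrocyte), -0.0038 to 0.068 (astrocyte), -0.16 to -0.084 (microglia), -0.12 to -0.015 (endothelial), -0.83 to -0.24 (meninges), 0.080 to 0.30 (blood cell) and -0.19 to -0.081 (sex-linked).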

Other observations

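The test in this part was chosen after the results were seen, as were the genes named. Glucocorticoid response genes and immediate early genes, which respond to stress and to neuronal activity, varied widely between arrays of the same genotype. Glucocorticoid scores were -0.39, -0.054, 0.099 and 0.31 in the wild-type arrays and -0.25, 0.040 and 0.32 in the knockout arrays. Immediate early scores were -0.056, -0.30, 0.37 and 0.093 in the wild-type arrays and 0.18, -0.25 and 0.087 in the knockout arrays. Their medians between genotypes had opposite signs in the sexes, 0.19 and -0.099 within males and -0.23 and 0.24 within females. The female values rest on 1 knockout array, and the difference between the sexes was not tested for these lists.

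Genes that lie close together and change together would be a hint of chromosome segments inherited from another strain, and this was tested as a hypothesis. Among the 83 genes with an unadjusted p under 0.001, 21 were higher and the others lower. They formed 11 pairs within 20 tested genes of each other, against a mean of 7.18 in 10000 random gene sets matched on level (permutation p = 0.0933, one-sided). Sspn, Arntl2 and Klhl42 were such neighbours, not adjacent, and differed by -0.29, -0.84 and -0.56, without passing over all genes. Of the 35 splits of the arrays, 17 gave as many pairs from as many genes, and the highest other count was 25. The clustering was not shown to be more than chance, and such segments are not excluded.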
